A study of Mus musculus with 24 samples.

How the data were processed

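RNA of 4 sorted CD4 T cell subsets was sequenced in 24 libraries, 3 for each of 8 groups of subset and treatment. Per the labels' protocols, RNA was purified on silica columns with DNase digestion, depleted of ribosomal RNA and made into total RNA libraries with a CORALL kit. Per the submitters' processing notes, STAR and featureCounts were used with the mm10 genome. Their versions, the annotation release, the strand setting and the handling of duplicate reads are not given in the sources used here. The authors deposited raw read counts per Ensembl gene in a table of 39056 genes, with no normalization, and whole numbers with different totals per library were found in it when checked. Symbols and coordinates (mm10, GRCm38) were taken from GENCODE release M21 by gene ID, which matched 38872 IDs and left 184 unmatched.

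Genes were tested with edgeR 4.0.16 in R 4.3.3. The filterByExpr filter by group kept 18789 genes, TMM factors scaled the libraries, and 1 model with 8 group means was fitted to all 24 libraries without covariates. The quasi-likelihood F test was two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The common biological coefficient of variation was 0.617. Fitted group by group it ran from 0.0751 in treated Tconv to 1.04 in control TFH libraries. The 10 comparisons were 4 of treated against control mice within a subset, 4 between subsets of control mice and 2 differences of treatment effects. Standard errors of log2 fold changes come from the same model. A gene without overlap has every CPM value of one group above every value of the other.

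The 20 gene lists, the comparisons, the test and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 20 lists within each comparison, and again with an estimated correlation and with fry. After the data were seen, 7 lists were added: heat shock, mitochondrially encoded mRNAs, podocytes, proximal tubule, distal nephron, endothelial cells and hepatocytes. For each treatment comparison the rule names up to 8 genes per direction by size of the log2 fold change, among genes past the threshold with non-overlapping groups and at least 5 CPM in the higher group. Predicted genes, pseudogenes, immunoglobulin genes and T cell receptor variable segments were left out. The other comparisons take 5 per direction. The rule adds the 4 members of each list with the smallest p and 16 genes fixed by name. The text gives a selection of these, made after their values were seen, together with genes from the same rule without the libraries holding kidney transcripts. Where a group had no read, folds were computed against a floor of 3 reads over the group.

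A library was taken to hold kidney transcripts where its podocyte markers summed to over 10 CPM and to at least 10 times the lowest library of its group. Alternatives were relative log expression factors, no low-count filter, DESeq2 1.42.0, limma voom with quality weights, only the libraries of the groups compared, the replicate number as a block, leaving out receptor, haemoglobin and mitochondrial genes, and leaving out each library. Alternatives added after the data were seen were the fit without the kidney libraries, for genes and lists, a fit of genes that also left out control TFH 3, thinning every library to 2.54 M counts, and a minimum mean of 10 CPM. Library totals ran from 2.54 to 53.8 M counts. The 95% Wilson interval of a share of counts given for 1 library reached at most 0.0440 percentage points to either side for mitochondrially encoded genes and 0.0132 for Gm42418. Libraries of a group differed by more than counting noise (lowest chi-square per degree of freedom 4.70), so none were merged.

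The test was tried on simulated data with 200 changed genes, none with a mean below 10 CPM, so recovery below that is unknown. Of 100 genes changed by a log2 fold of 1, it recovered 51, 53, 63 and 45% for treatment in Tconv, Treg, TFH and TFR cells. At a log2 fold of 2 it recovered 85, 93, 91 and 84%, with 18162 to 18202 genes tested. Between control subsets it recovered 55, 55, 49 and 46% at a log2 fold of 1 and 87, 87, 78 and 83% at 2. These are Treg against Tconv, TFR against TFH, TFH against Tconv and TFR against Treg, with 18159 to 18175 genes tested. In 2 further simulations per comparison of 2 groups, no gene differed between them, and only there did the libraries of each group have their own spread. They gave 3 and 0 false calls for treatment in Tconv, 1 and 1 in Treg and 3 and 9 for Treg against Tconv cells. In them 18160 to 18201 genes were tested. For the comparisons with control TFH or TFR libraries the numbers stand with the results. Reads of genes whose exons overlap another gene, or an antisense one, may be split wrongly, so values of Arhgap23, Bcl6, Cxcr5, Ddn, Dusp1, Foxp3, Gapdh, Hif1a, Il12rb2, Notch1, Notch3, Pcdh19 and Thbs1 are uncertain. The same holds for near-identical copies (Hspa1a, Hspa1b, Ccl3, Ccl4, granzymes, immunoglobulin constant genes, Gapdh, Ldha and Tpi1 with their pseudogenes, and mitochondrial genes). Figures were drawn with matplotlib 3.10.9, and tables read with pandas 2.3.3.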

Results

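Total RNA was sequenced from 4 sorted CD4 T cell subsets of female NZBWF1/j mice, a hybrid strain that develops a lupus-like autoimmune disease. Treated mice had received recombinant mouse OX40L, the ligand of the costimulatory receptor OX40, together with JAG1, a ligand of Notch receptors. Each protein was given into the peritoneum at 2 mg/kg once weekly for 3 doses from 23 weeks of age, control mice received PBS, and cells were collected at week 26. The subsets were conventional cells (Tconv, CXCR5-negative and GITR-negative), regulatory cells (Treg, CXCR5-negative and GITR-positive), follicular helper cells (TFH, CXCR5-positive, PD1-high, GITR-negative or low) and follicular regulatory cells (TFR, CXCR5-positive, PD1-high, GITR-high). Each of the 8 groups held 3 libraries. Nothing in the labels says that these came from separate mice, so p-values measure only the spread between the 24 libraries, which may be technical. The depth per library, in M (mega) counts and in the order of library numbers, was 43.9, 37.3 and 39.2 M in treated Tconv, 50.2, 53.8 and 38.2 M in treated Treg, 34.5, 31.8 and 37.8 M in treated TFH and 41.7, 50.9 and 35.4 M in treated TFR libraries. It was 24.7, 27.5 and 33.2 M in control Tconv, 27.1, 27.4 and 28 M in control Treg, 5.74, 2.54 and 15.2 M in control TFH and 9.62, 8.52 and 4.85 M in control TFR libraries. Expression is given in CPM, counts scaled to a common library total, as mean ± SD of the 3 libraries of a group, treated first. Log2 fold changes (log2FC) carry their standard error, and intervals and floors cover counting error only.

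Some properties of the libraries went along with the groups. With each library thinned to the size of the smallest, control TFH and TFR libraries showed 11777 ± 1418 and 12341 ± 591 detected genes, against 17288 ± 1020.1 in treated TFH, 16472 ± 974 in treated TFR, 16761 ± 1504 in control Tconv and 14846 ± 77.3 in control Treg libraries. Mitochondrially encoded genes took 10.3 ± 0.946% of the counts in control Tconv, 10.7 ± 0.944% in control Treg, 16 ± 0.921% in control TFH and 10.6 ± 0.663% in control TFR libraries. In treated libraries these shares were 2.46 ± 0.186%, 2.0 ± 0.179%, 2.75 ± 0.517% and 2.52 ± 0.0451%. Kidney cell transcripts stood out most in 5 libraries. Markers of podocytes, the filtration cells of the kidney, summed to 714 and 736 CPM in control Tconv libraries 1 and 2, 749.6 CPM in treated TFH 3, 359 CPM in treated TFR 1 and 87.8 CPM in treated Treg 3, and to at most 6.04 CPM elsewhere. Proximal tubule markers summed to 1029, 1084, 1046, 522 and 132 CPM in the same libraries, 31.8 CPM in control TFH 3 and at most 3.75 CPM in the other 18. There were 495 tested genes above the other libraries of the group in all 5 of these, and they are called kidney-raised below. Counts of genes are therefore also given without the 5 libraries, an alternative chosen after the data were seen, which keeps control TFH 3.

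**Figure D1:**
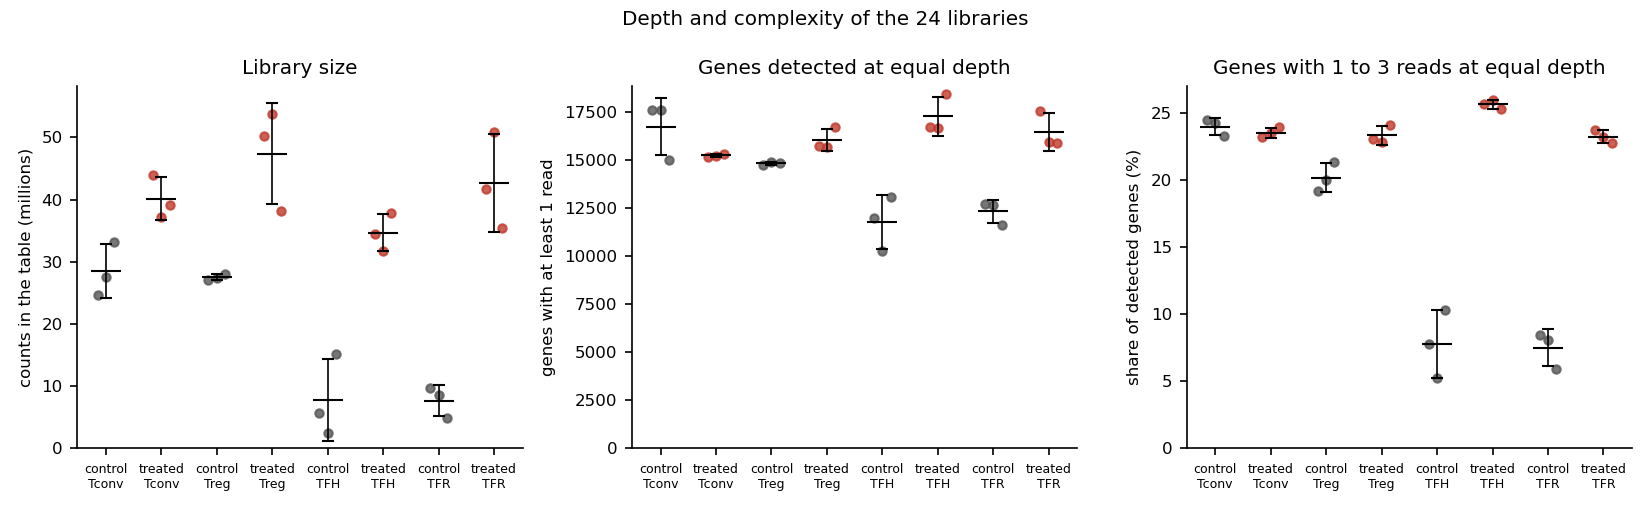
Library size in M counts, genes detected after thinning to the smallest library, and the share of detected genes with 1 to 3 reads, per library (points) with group mean and SD (bars). Control TFH and TFR libraries lie at 10271 to 13086 genes, below the 14762 or more of the other 18 libraries.

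The first comparisons set treated against control mice in each subset, where handling or batch cannot be told apart from OX40L-JAG1 treatment. In Tconv cells, immediate early genes, genes of T cell identity and helper and effector cytokines were higher in treated than in control mice. Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273), a subunit of the AP-1 transcription factor, was at 2668 ± 22.9 against 303 ± 36.4 CPM (log2FC 3.14 ± 0.16, adjusted p = 2.1e-11). Gzmk (ENSMUSG00000042385.14, chromosome 13, 113171608 to 113225908), a granule protease of effector T cells, was at 32.4 ± 1.70 against 0.910 ± 0.263 CPM (log2FC 5.15 ± 0.45, adjusted p = 3.1e-08). Ccl5 (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518), a chemokine of effector cells, was at 48.5 ± 0.714 against 4.96 ± 1.18 CPM (log2FC 3.29 ± 0.21, adjusted p = 3.7e-10). Ifng (ENSMUSG00000055170.4, chromosome 10, 118441046 to 118445892), the Th1 cytokine, was at 42.8 ± 0.713 against 2.10 ± 1.07 CPM (log2FC 4.33 ± 0.28, adjusted p = 2.8e-10). Cd3g (ENSMUSG00000002033.14), a chain of the T cell receptor complex, was at 594 ± 24.3 against 178 ± 16.1 CPM (log2FC 1.74 ± 0.12, adjusted p = 1.1e-09). Neurl3 (ENSMUSG00000047180.8), a ubiquitin ligase, was lower, at 105 ± 3.74 against 558 ± 86.2 CPM (log2FC -2.41 ± 0.10, adjusted p = 2.0e-12).

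Of the activation and immediate early list, 17 of 23 rose and 1 fell (19 and 2 adjusted over the list alone), with a camera adjusted p of 6.3e-54. Fosb (ENSMUSG00000003545.3), another AP-1 subunit, was at 967 ± 9.78 against 90.9 ± 16.3 CPM (log2FC 3.41 ± 0.18, adjusted p = 2.2e-11). Dusp1 (ENSMUSG00000024190.6), a phosphatase that limits MAP kinase signalling, was at 2034 ± 41 against 446 ± 66.6 CPM (log2FC 2.19 ± 0.10, adjusted p = 2.6e-12). Heat shock genes rose alongside, 13 of 14 measured, with summed levels of 21694 ± 470.3 against 6417 ± 218 CPM, while 12 of 13 mitochondrially encoded mRNAs fell. Of the T cell identity list 17 of 18 rose and 0 fell (17 and 1 adjusted over the list alone), camera adjusted p = 4.0e-31. Thy1 (ENSMUSG00000032011.5) was at 567 ± 34.6 against 166 ± 16.2 CPM (log2FC 1.78 ± 0.12, adjusted p = 1.3e-09). Of helper and effector cytokines 8 of 28 rose and 0 fell (13 and 0 adjusted over the list alone), camera adjusted p = 1.2e-15. Of glycolysis genes 13 of 19 rose and 0 fell (16 and 0 adjusted over the list alone), camera adjusted p = 4.3e-10. Of type I interferon response genes 15 of 36 rose and 0 fell (19 and 0 adjusted over the list alone), camera adjusted p = 7.4e-09. Of the TFH program 11 of 24 rose and 2 fell (11 and 3 adjusted over the list alone), camera adjusted p = 9.9e-09. Its members went apart. Cxcr5 (ENSMUSG00000047880.15, chromosome 9, 44511787 to 44561877), the follicle homing receptor, rose to 15.6 ± 0.951 against 1.83 ± 0.891 CPM (log2FC 3.10 ± 0.26, adjusted p = 2.3e-08). Bcl6 (ENSMUSG00000022508.5, chromosome 16, 23965052 to 23988852), the lineage factor of TFH cells, fell to 34.2 ± 0.669 against 52 ± 5.25 CPM (log2FC -0.60 ± 0.12, adjusted p = 0.0014). Of co-inhibitory receptors 7 of 16 rose and 1 fell (7 and 1 adjusted over the list alone), camera adjusted p = 7.2e-07. Ctla4 (ENSMUSG00000026011.13, chromosome 1, 60887000 to 60915832) was at 103 ± 6.35 against 35.8 ± 3.55 CPM (log2FC 1.53 ± 0.09, adjusted p = 7.9e-11). Of proliferation genes 7 of 35 rose and 1 fell (10 and 1 adjusted over the list alone), camera adjusted p = 2.4e-05. Mki67 (ENSMUSG00000031004.8) was at 63.3 ± 4.51 against 9.87 ± 6.24 CPM (log2FC 2.69 ± 0.34, adjusted p = 7.2e-06).

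Of the Treg program 8 of 26 rose and 4 fell (8 and 6 adjusted over the list alone), camera adjusted p = 3.4e-05, or adjusted p = 0.053 with an estimated correlation. Its median log2FC of 0.09 turned to -0.02 with relative log expression scaling and to 1.54 without the 5 libraries, which leaves 1 control Tconv library. Foxp3 (ENSMUSG00000039521.12, chromosome X, 7573644 to 7595245), the defining factor of regulatory cells, was at 11.9 ± 1.08 against 5.81 ± 1.32 CPM (log2FC 1.04 ± 0.20, adjusted p = 0.0012). Tnfrsf18 (ENSMUSG00000041954.18), the gene of GITR, was at 32.1 ± 1.90 against 71 ± 12.7 CPM (log2FC -1.15 ± 0.14, adjusted p = 3.7e-06). OX40 and NF-kB signalling had 9 higher and 4 lower of 25, or 10 and 4 adjusted over the list alone, camera adjusted p = 0.00013. That call was lost with an estimated correlation (adjusted p = 0.14) and with 1 control library left. Tnfrsf4 (ENSMUSG00000029075.6, chromosome 4, 156013843 to 156016612), encoding OX40 itself, was at 30.8 ± 0.727 against 27.5 ± 2.82 CPM and did not pass (adjusted p = 0.54). Of Notch pathway genes and targets 2 of 20 rose and 0 fell (2 and 0 adjusted over the list alone), camera adjusted p = 0.90. Dtx1 (ENSMUSG00000029603.15, chromosome 5, 120680202 to 120711927), a Notch target, was at 200.3 ± 12.3 against 48 ± 7.16 CPM (log2FC 2.06 ± 0.61, adjusted p = 0.034). Notch1 (ENSMUSG00000026923.15, chromosome 2, 26457903 to 26516663) was at 324 ± 6.14 against 237 ± 31.5 CPM (log2FC 0.45 ± 0.14, adjusted p = 0.040). Hes1 (ENSMUSG00000022528.7) was at 0.694 ± 0.207 against 8.42 ± 6.95 CPM (adjusted p = 0.18) and the kidney-raised Notch3 (ENSMUSG00000038146.7) at 0.103 ± 0.115 against 21 ± 18.1 CPM (adjusted p = 0.12). IL-2 and STAT5 signalling (5 higher and 2 lower of 17, or 5 and 2 adjusted over the list alone), apoptosis regulators (4 and 2 of 24, or 5 and 2), oxidative phosphorylation (3 and 1 of 33, or 5 and 1) and plasma cell markers (4 and 1 of 14, or 4 and 1) were called upward, with camera adjusted p of 0.0030, 0.010, 0.028 and 0.033. With an estimated correlation these gave adjusted p = 0.14, 0.053, 0.23 and 0.053, and were lost with 1 control library left. Of CD8 and NK cell markers 2 of 12 rose and 0 fell (2 and 0 adjusted over the list alone), camera adjusted p = 0.0044. This was lost with 1 control library left. Their sums were 163 ± 4.19 against 54.5 ± 7.08 CPM. B cell marker sums were 391 ± 16 against 168 ± 23.7 CPM. B cell markers (2 higher and 0 lower of 21, or 3 and 1 adjusted over the list alone), myeloid and dendritic cell markers (1 and 0 of 17, or 1 and 0), erythroid and platelet markers and naive and recirculation genes (4 and 2 of 16, or 5 and 3) were not called, with camera adjusted p of 0.39, 0.52, 0.067 and 0.067.

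In total 1294 genes were higher and 574 lower in treated Tconv cells by edgeR's quasi-likelihood test at an adjusted p under 0.05, of 18789 tested. Relative log expression scaling shifted the median of all genes by -0.10 and gave 1062 higher and 746 lower. 43% of tested genes had group values that did not overlap (10% by chance). Of the lower genes 61 were kidney-raised, including all 8 that the naming rule selects (Arhgap23, Arhgap24, Bcam, Fn1, Mertk, Plxna2, Tjp1 and Tns3). Plxna2 (ENSMUSG00000026640.12) had 0 reads in treated libraries and 90.4 ± 78 CPM in controls, at least 3102-fold lower against a floor of 3 reads over the group. Over its alternatives Fos had adjusted p of 1.7e-91 to 5.7e-06. Without the 5 libraries, with 1 control library left, the log2FC of Ifng, Cxcr5 and Mki67 was 3.71, 4.24 and 4.49. The total was 1172 without control Tconv 1, 1211 without control Tconv 2 and 1215 without treated Tconv 2, and 5629 when fitted on the 6 libraries compared.

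In Treg cells, treated mice showed higher proliferation and glycolysis genes and lower genes of the naive and recirculating state. Top2a (ENSMUSG00000020914.17, chromosome 11, 98992943 to 99024189), a topoisomerase of dividing cells, rose to 324 ± 4.23 against 68.9 ± 3.89 CPM (log2FC 2.23 ± 0.10, adjusted p = 5.9e-13). Mki67, the Ki-67 proliferation antigen, was at 884 ± 47.4 against 109 ± 16.5 CPM (log2FC 3.02 ± 0.33, adjusted p = 1.5e-06). Satb1 (ENSMUSG00000023927.15, chromosome 17, 51736187 to 51833290), a chromatin organiser, fell to 186 ± 4.36 against 766 ± 11 CPM (log2FC -2.04 ± 0.10, adjusted p = 2.3e-12). Ccr7 (ENSMUSG00000037944.8, chromosome 11, 99144196 to 99155077), a lymph node homing receptor, was at 183 ± 14.1 against 758 ± 30 CPM (log2FC -2.05 ± 0.11, adjusted p = 1.3e-11). Scin (ENSMUSG00000002565.16), an actin-severing protein, was at 112 ± 5.61 against 5.21 ± 2.19 CPM (log2FC 4.42 ± 0.40, adjusted p = 2.4e-07). The Treg genes Ikzf2 (ENSMUSG00000025997.13, chromosome 1, 69531214 to 69687245), encoding Helios, and Il2ra (ENSMUSG00000026770.5, chromosome 2, 11642807 to 11693193), encoding CD25, rose to 1185 ± 13.5 against 640.2 ± 20 CPM (log2FC 0.89 ± 0.12, adjusted p = 1.4e-05) and 216 ± 3.93 against 113 ± 14.3 CPM (log2FC 0.93 ± 0.17, adjusted p = 0.00090), whereas Foxp3 at 549 ± 41.2 against 473 ± 30.6 CPM (adjusted p = 0.62) and Ctla4 at 629.7 ± 17.1 against 579 ± 7.88 CPM (adjusted p = 0.51) did not pass.

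Of the proliferation list 26 of 35 rose and 0 fell (31 and 1 adjusted over the list alone), camera adjusted p = 1.3e-28. Of naive and recirculation genes 1 of 16 rose and 9 fell (1 and 9 adjusted over the list alone), camera adjusted p = 9.1e-24. Bach2 (ENSMUSG00000040270.16) was at 58.7 ± 1.56 against 266 ± 12.1 CPM (log2FC -2.18 ± 0.15, adjusted p = 1.3e-09). Of glycolysis genes 12 of 19 rose and 1 fell (15 and 1 adjusted over the list alone), camera adjusted p = 6.4e-12. Ldha (ENSMUSG00000063229.15) was at 505 ± 45.3 against 276 ± 20.4 CPM (log2FC 0.87 ± 0.11, adjusted p = 1.5e-05). Of interferon response genes 10 of 36 rose and 0 fell (15 and 0 adjusted over the list alone), camera adjusted p = 1.8e-05. Of activation and immediate early genes 11 of 23 rose and 2 fell (13 and 3 adjusted over the list alone), camera adjusted p = 4.2e-09, or adjusted p = 0.084 with an estimated correlation. Fos was at 1490.0 ± 78.8 against 167 ± 10.8 CPM (log2FC 3.16 ± 0.16, adjusted p = 1.0e-11). Heat shock genes were higher in 13 of 14, at 11461 ± 234 against 3782 ± 385 CPM in sum, and 12 of 13 mitochondrially encoded mRNAs were lower. B cell markers had 5 of 21 higher and 0 lower (6 and 1 adjusted over the list alone), camera adjusted p = 0.0024, or adjusted p = 0.084 without the 5 libraries. Their sum was 1227 ± 50.9 against 298 ± 43.8 CPM. Cd74 (ENSMUSG00000024610.14), the class II invariant chain, was at 196 ± 13.9 against 68.8 ± 3.42 CPM (log2FC 1.51 ± 0.16, adjusted p = 8.7e-07). Of T cell identity genes 6 of 18 rose and 1 fell (9 and 2 adjusted over the list alone), camera adjusted p = 0.038, or adjusted p = 0.59 with an estimated correlation. The Treg program had 6 higher and 4 lower of 26, or 8 and 5 adjusted over the list alone, the TFH program 4 and 4 of 24, or 4 and 7, OX40 and NF-kB signalling 6 and 4 of 25, or 6 and 6 and Notch genes 2 and 2 of 20, or 3 and 2, with camera adjusted p of 0.44, 0.35, 0.52 and 0.68. Pdcd1 (ENSMUSG00000026285.7, chromosome 1, 94038305 to 94052553), encoding PD-1, fell to 72 ± 6.25 against 222 ± 20.1 CPM (log2FC -1.62 ± 0.16, adjusted p = 3.1e-07). Without the 5 libraries 1 Notch gene was higher and 0 lower. Dtx1 was at 136 ± 14.3 against 24.1 ± 3.22 CPM (log2FC 2.49 ± 0.62, adjusted p = 0.012), while Tnfrsf4 was at 274 ± 21.7 against 254 ± 6.02 CPM (adjusted p = 0.76).

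In total 972 genes were higher and 668 lower in treated Treg cells (edgeR), and 1153 and 471 when receptor, haemoglobin and mitochondrial genes were left out of the scaling. 46.4% of tested genes had group values that did not overlap (10% by chance). With the 5 libraries left out 652 were higher and 332 lower, with 5 interferon response genes higher. Leaving out any 1 library gave 1062 to 1119 genes, with 1091 without control Treg 2 and 1068, 1062 and 1093 without treated Treg 1, 2 and 3, and the fit of the 6 libraries compared gave 6190. Control Treg 3 stood apart in that the single non-coding gene Gm42418 took 14.9% of its counts, against 0.709% and 0.377% in control Treg 1 and 2.

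In TFH cells, treated mice showed higher cytotoxic and effector genes, immediate early genes and proliferation genes, with lower Pdcd1 and Icos. Eomes (ENSMUSG00000032446.14), a transcription factor of cytotoxic and effector cells, rose to 538 ± 87.8 against 41.3 ± 4.70 CPM (log2FC 3.71 ± 0.30, adjusted p = 8.3e-09). Ccl5 rose to 222 ± 33.4 against 12.7 ± 3.39 CPM (log2FC 4.18 ± 0.23, adjusted p = 2.1e-11). Gzmk was at 177 ± 24.1 against 9.02 ± 7.60 CPM (log2FC 4.46 ± 0.43, adjusted p = 1.6e-07). Nkg7 (ENSMUSG00000004612.9), a protein of cytotoxic granules, was at 79.7 ± 6.99 against 0.968 ± 1.05 CPM (log2FC 6.22 ± 0.82, adjusted p = 2.0e-05). Pdcd1 fell to 146 ± 8.12 against 286 ± 17.6 CPM (log2FC -0.97 ± 0.16, adjusted p = 0.00014). Icos (ENSMUSG00000026009.14), a costimulatory receptor of TFH cells, was at 355 ± 53.6 against 575 ± 36.6 CPM (log2FC -0.70 ± 0.11, adjusted p = 0.00013). Bcl6 was at 151 ± 14.2 against 208 ± 29.9 CPM (log2FC -0.46 ± 0.12, adjusted p = 0.0087), Il21 (ENSMUSG00000027718.8, chromosome 3, 37222759 to 37232636), a cytokine of B cell help, at 61 ± 4.09 against 26.3 ± 10.9 CPM (log2FC 1.22 ± 0.33, adjusted p = 0.010) and Tnfrsf4 at 95.2 ± 5.37 against 143 ± 29.6 CPM (log2FC -0.59 ± 0.14, adjusted p = 0.0033). The 6 TFH libraries fitted alone gave adjusted p of 0.093, 0.068 and 0.082, and all alternatives ranges of 0.00016 to 0.14, 0.00043 to 0.068 and 4.4e-05 to 0.082. Foxp3 was at 50.8 ± 8.14 against 47.3 ± 18.9 CPM (adjusted p = 0.80).

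Several genes had no read in any control TFH library, which may hold few RNA molecules. Scin was at 39.8 ± 6.98 CPM in treated cells, at least 306-fold higher. Cit (ENSMUSG00000029516.19), a kinase of cell division, was at 33.5 ± 2.46 CPM, at least 257-fold, and Dpysl5 (ENSMUSG00000029168.14) at 28.4 ± 1.48 CPM, at least 218-fold. Gcg (ENSMUSG00000000394.15), the glucagon precursor, was at 23.2 ± 1.98 CPM, at least 178-fold. Olig2 (ENSMUSG00000039830.8), a transcription factor of neural lineages, was lower, at 3.31 ± 0.508 against 68.7 ± 37.1 CPM (log2FC -4.37 ± 0.43, adjusted p = 1.9e-07). Of activation and immediate early genes 16 of 23 rose and 3 fell (17 and 3 adjusted over the list alone), camera adjusted p = 8.2e-24. Fos was at 1973 ± 129 against 235 ± 21.7 CPM (log2FC 3.07 ± 0.16, adjusted p = 1.6e-11) and Hif1a (ENSMUSG00000021109.13), the hypoxia factor, at 977 ± 102 against 1936 ± 128 CPM (log2FC -0.99 ± 0.09, adjusted p = 7.5e-08). Heat shock genes rose in 13 of 14 (14545 ± 1776 against 4343 ± 111 CPM in sum) and 12 of 13 mitochondrially encoded mRNAs fell. Of proliferation genes 21 of 35 rose and 1 fell (26 and 2 adjusted over the list alone), camera adjusted p = 3.8e-11. Of glycolysis genes 15 of 19 rose and 1 fell (16 and 1 adjusted over the list alone), camera adjusted p = 1.3e-09. Of helper and effector cytokines 10 of 28 rose and 0 fell (11 and 1 adjusted over the list alone), camera adjusted p = 0.0016. Ifng was at 109 ± 12.3 against 28.5 ± 1.47 CPM (log2FC 1.94 ± 0.25, adjusted p = 7.4e-06). Of CD8 and NK cell markers 6 of 12 rose and 0 fell (6 and 1 adjusted over the list alone), camera adjusted p = 0.0094, at 663 ± 123 against 59.3 ± 10.5 CPM in sum. Plasma cell markers were called upward with 5 higher and 1 lower of 14, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.029, or adjusted p = 0.063 with an estimated correlation), with Igkc (ENSMUSG00000076609.2), the kappa light chain, at 992 ± 113 against 102 ± 30.2 CPM (log2FC 3.27 ± 0.16, adjusted p = 5.0e-12). The B cell marker sum was 2688 ± 350.1 against 611 ± 55.6 CPM. Of the Treg program 5 of 26 rose and 9 fell (5 and 10 adjusted over the list alone), camera adjusted p = 0.0052 downward, or adjusted p = 0.25 with an estimated correlation, while its mean log2FC was 0.39 and its median -0.02. T cell identity had 8 higher and 1 lower of 18, or 10 and 1 adjusted over the list alone, camera adjusted p = 0.0031, or adjusted p = 0.49 with an estimated correlation. The TFH program had 6 higher and 5 lower of 24, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.73), with Cxcr5 at 261 ± 20.9 against 121 ± 22 CPM (log2FC 1.12 ± 0.23, adjusted p = 0.0014). Notch genes had 4 higher and 1 lower of 20, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.42), with Notch1 at 519 ± 29.4 against 202 ± 34.7 CPM (log2FC 1.36 ± 0.14, adjusted p = 4.2e-07). Rbpj (ENSMUSG00000039191.12), the DNA-binding partner of Notch, was at 70.7 ± 8.01 against 114 ± 3.18 CPM (log2FC -0.69 ± 0.11, adjusted p = 0.00013).

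In total 3099 genes were higher and 1101 lower in treated TFH cells (edgeR), with a median log2FC over all genes of 0.42, and 1712 and 1103 with every library thinned to 2.54 M counts. 35.3% of tested genes had group values that did not overlap (10% by chance), and 1307 of the higher genes had 0 reads in control libraries. In 2 simulations without any change, the 24-library fit called 831 of 18175 and 864 of 18172 genes. The fit of the 6 libraries compared called 0 of 14049 and 2 of 14103 in them. On the real counts that fit gave 1299 higher and 343 lower. Without the 5 libraries 1622 were higher and 547 lower, and 49 of the 3099 higher genes were kidney-raised, among them Ddn, Filip1 and Lama5 of those the naming rule selects. Gm42418 took 10.4% of the counts of treated TFH 3, against 0.585% and 1.32% in treated TFH 1 and 2.

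In TFR cells, treated mice showed higher glycolysis, oxidative phosphorylation, proliferation and effector genes and lower genes of the TFH program. Gapdh (ENSMUSG00000057666.18) rose to 1046 ± 71.3 against 417 ± 51.3 CPM (log2FC 1.33 ± 0.10, adjusted p = 3.2e-09). Ldha was at 826 ± 54.1 against 246 ± 10.3 CPM (log2FC 1.75 ± 0.12, adjusted p = 5.9e-10). Atp5b (ENSMUSG00000025393.12), a subunit of the mitochondrial ATP synthase, rose to 693 ± 26.1 against 383 ± 9.35 CPM (log2FC 0.86 ± 0.06, adjusted p = 3.2e-09). Bcl6 fell to 54.8 ± 2.70 against 141 ± 15.5 CPM (log2FC -1.36 ± 0.12, adjusted p = 4.2e-08). Pdcd1 was at 142 ± 13.7 against 369 ± 47.8 CPM (log2FC -1.38 ± 0.16, adjusted p = 1.8e-06). Foxp3 rose to 561 ± 54.1 against 354 ± 39.6 CPM (log2FC 0.67 ± 0.18, adjusted p = 0.012), Il2ra to 188 ± 11 against 66.8 ± 3.60 CPM (log2FC 1.49 ± 0.18, adjusted p = 2.6e-06) and Tnfrsf4 to 410.3 ± 30.5 against 267 ± 54.5 CPM (log2FC 0.62 ± 0.13, adjusted p = 0.0019). Batf (ENSMUSG00000034266.5), an AP-1 family factor of effector Treg cells, rose to 163 ± 21.9 against 54.8 ± 4.87 CPM (log2FC 1.58 ± 0.14, adjusted p = 5.4e-08). Ccl5 was at 245 ± 9.22 against 9.05 ± 3.49 CPM (log2FC 4.74 ± 0.23, adjusted p = 5.5e-12). Gzmb (ENSMUSG00000015437.4), granzyme B, was at 77.9 ± 9.22 against 1.35 ± 1.85 CPM (log2FC 5.80 ± 0.82, adjusted p = 4.1e-05). Nkg7, Ccl4 (ENSMUSG00000018930.3), a chemokine, and Ret (ENSMUSG00000030110.13), a receptor kinase, had no read in control TFR libraries. They were at 57.6 ± 1.72, 52.4 ± 0.598 and 26.5 ± 3.37 CPM in treated ones, at least 477-, 433- and 218-fold higher by counting error alone. Olig2 fell to 0.875 ± 0.313 against 52.8 ± 11.5 CPM (log2FC -5.91 ± 0.46, adjusted p = 6.3e-09).

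Of glycolysis genes 15 of 19 rose and 1 fell (16 and 1 adjusted over the list alone), camera adjusted p = 2.0e-19. Of oxidative phosphorylation genes 19 of 33 rose and 0 fell (20 and 0 adjusted over the list alone), camera adjusted p = 7.1e-07, while 11 of 13 mitochondrially encoded mRNAs fell. Of proliferation genes 23 of 35 rose and 0 fell (28 and 0 adjusted over the list alone), camera adjusted p = 1.6e-14. Top2a was at 491 ± 39.7 against 178 ± 8.49 CPM (log2FC 1.46 ± 0.09, adjusted p = 2.5e-10). Of activation and immediate early genes 14 of 23 rose and 1 fell (16 and 1 adjusted over the list alone), camera adjusted p = 3.5e-11. Heat shock genes rose in 14 of 14 (11202 ± 345 against 3553 ± 149.6 CPM in sum). Of helper and effector cytokines 14 of 28 rose and 0 fell (16 and 0 adjusted over the list alone), camera adjusted p = 3.2e-05. Tnf (ENSMUSG00000024401.14) was at 139 ± 7.94 against 56.9 ± 23.7 CPM (log2FC 1.28 ± 0.20, adjusted p = 7.9e-05). Of B cell markers 6 of 21 rose and 0 fell (7 and 0 adjusted over the list alone), camera adjusted p = 4.7e-08, at 2710.3 ± 90.6 against 442 ± 36.7 CPM in sum. Of plasma cell markers 8 of 14 rose and 0 fell (8 and 0 adjusted over the list alone), camera adjusted p = 5.9e-05. Jchain (ENSMUSG00000067149.6) was at 109 ± 5.33 against 4.47 ± 2.23 CPM (log2FC 4.67 ± 0.29, adjusted p = 1.7e-10). Of CD8 and NK cell markers 6 of 12 rose and 0 fell (6 and 0 adjusted over the list alone), camera adjusted p = 0.00050, at 345 ± 22.3 against 38.1 ± 8.0 CPM in sum. Of the TFH program 3 of 24 rose and 8 fell (3 and 8 adjusted over the list alone), camera adjusted p = 0.0013 downward with a median of -0.17 and a mean of 0.01. Of naive and recirculation genes 3 of 16 rose and 6 fell (3 and 6 adjusted over the list alone), camera adjusted p = 0.0013 downward with a mean of 0.48, or adjusted p = 0.21 with an estimated correlation. T cell identity (10 higher and 2 lower of 18, or 10 and 2 adjusted over the list alone), IL-2 and STAT5 signalling (8 and 1 of 17, or 8 and 1) and apoptosis regulators (6 and 1 of 24, or 6 and 2) had camera adjusted p of 0.0010, 0.045 and 0.045. These calls were lost with an estimated correlation (adjusted p = 0.33, 0.38 and 0.16). The Treg program had 11 higher and 2 lower of 26, or 12 and 3 adjusted over the list alone and Notch genes 7 and 3 of 20, or 8 and 3, not called by camera (adjusted p = 0.34 and 0.47). Dtx1 was at 117 ± 19.6 against 7.68 ± 10.1 CPM (log2FC 3.86 ± 0.69, adjusted p = 0.00032), Notch1 at 375 ± 12.6 against 200.5 ± 48.5 CPM (log2FC 0.90 ± 0.14, adjusted p = 6.7e-05) and Notch2 (ENSMUSG00000027878.11) at 135 ± 7.38 against 220.0 ± 44.8 CPM (log2FC -0.70 ± 0.13, adjusted p = 0.00042). Nrarp (ENSMUSG00000078202.3), a Notch target, was at 9.05 ± 0.930 against 2.44 ± 0.678 CPM (log2FC 1.89 ± 0.35, adjusted p = 0.00042), with adjusted p = 0.059 in the fit of the 6 TFR libraries alone and 4.8e-11 to 0.059 over its alternatives.

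In total 2934 genes were higher and 1200 lower in treated TFR cells (edgeR), with a median over all genes of 0.40, and 1563 and 1253 with every library thinned. Leaving receptor, haemoglobin and mitochondrial genes out of the scaling shifted that median by 0.11. 43.3% of tested genes had group values that did not overlap (10% by chance), and 1169 of the higher genes had 0 reads in control libraries. In simulations without any change 209 of 18147 and 182 of 18141 genes were called. Without the 5 libraries 1832 were higher and 655 lower, with 5 TFH program genes lower and 5 plasma cell markers higher, and 28 of the 2934 higher genes were kidney-raised, among them Arhgef17, Magi2 and Thbs1 of those the naming rule selects.

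**Figure D2:**
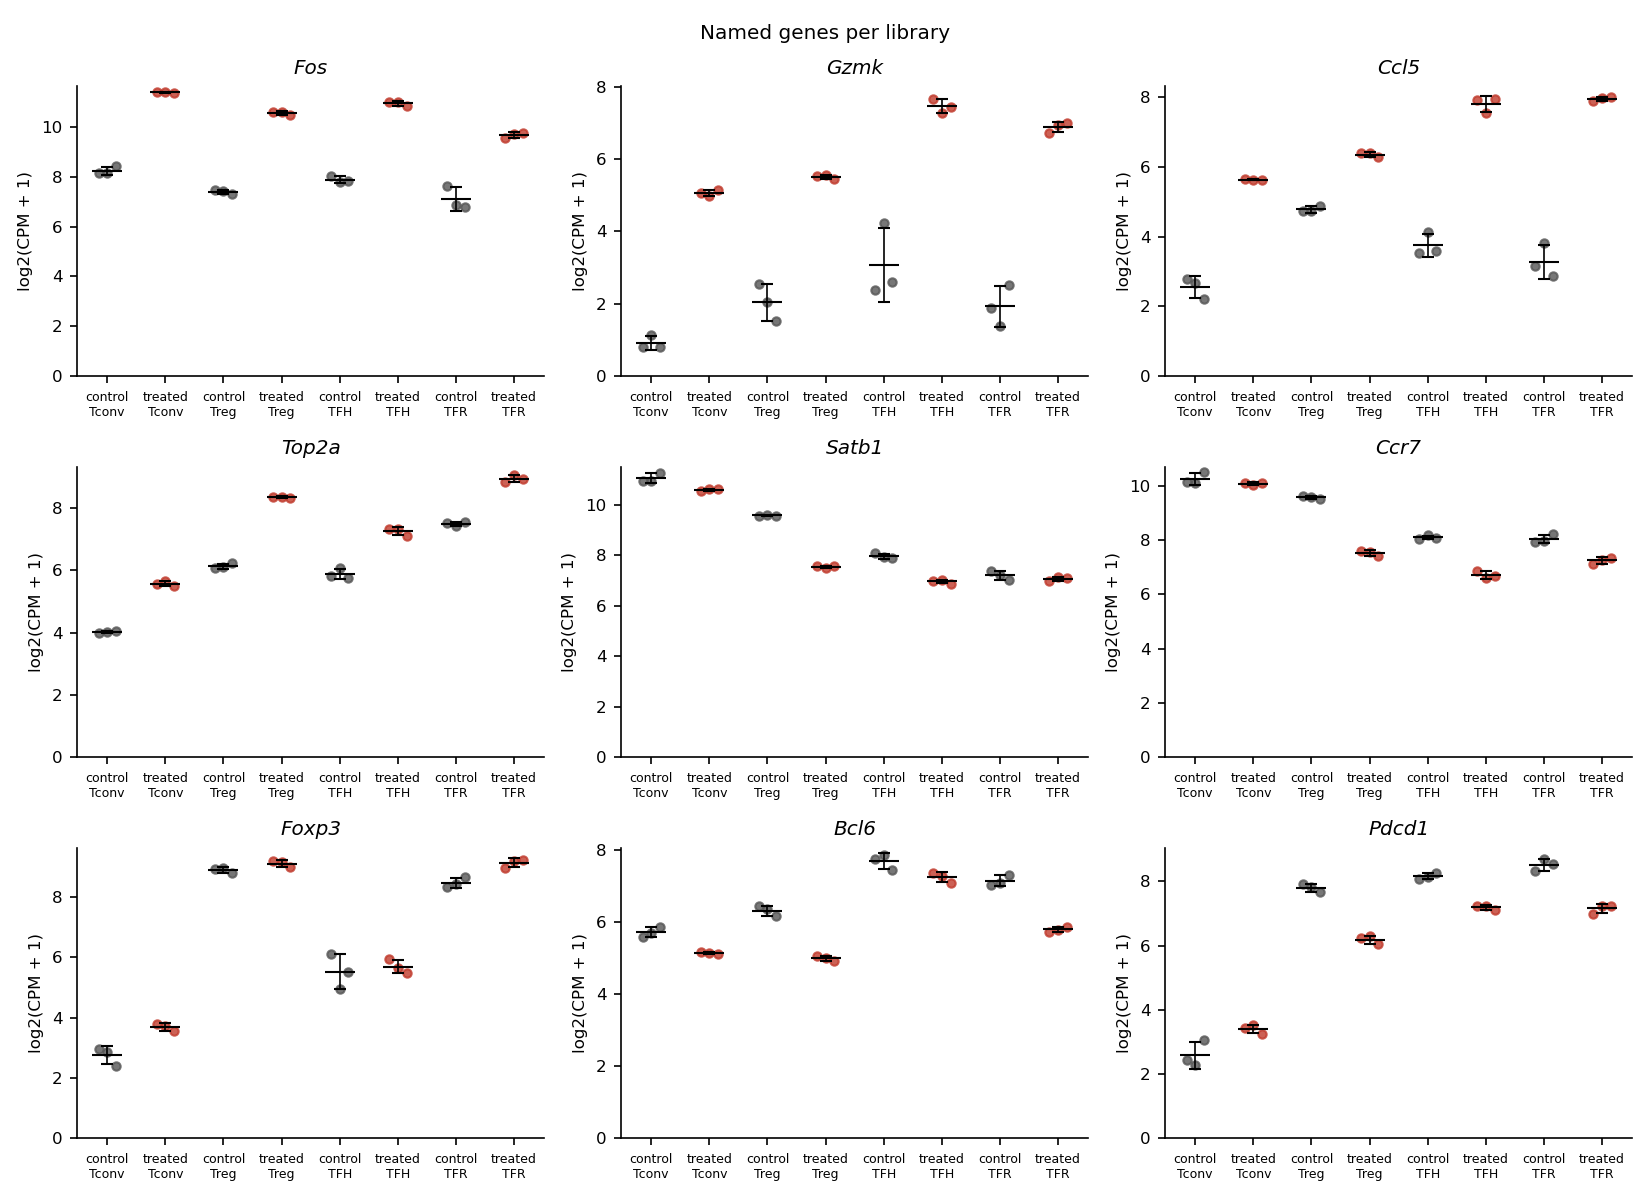
Expression of 9 named genes, log2(CPM + 1), in each library (points; grey control, red treated) of the 4 subsets, with mean and SD (bars). Fos lies above its controls in every subset, with 2668 against 303 CPM in Tconv cells, and Foxp3 is at 473 CPM in control Treg and 5.81 CPM in control Tconv cells.

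**Figure D3:**
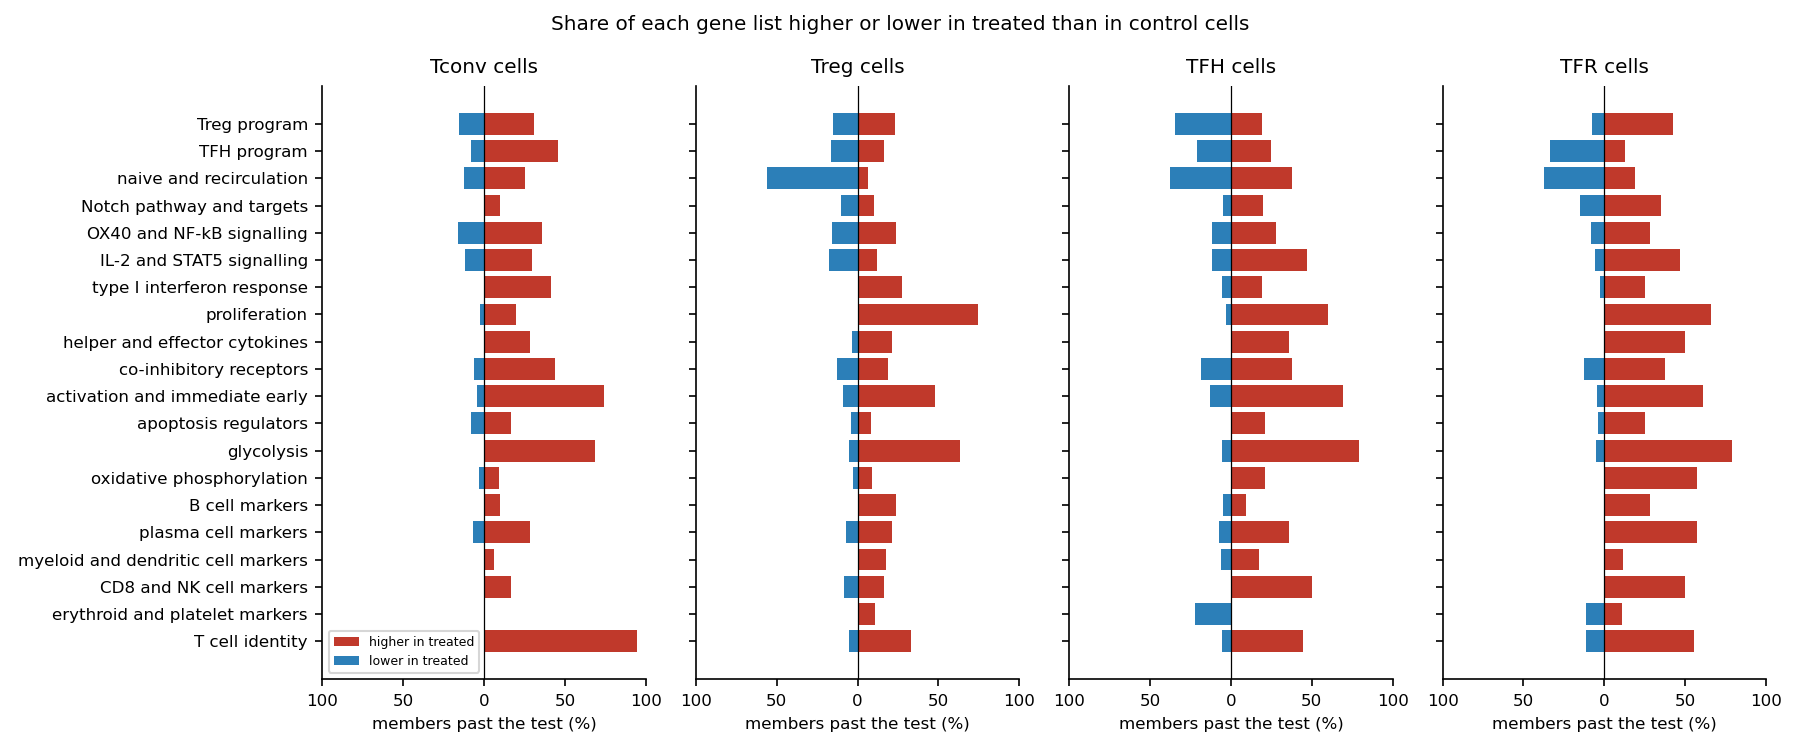
Percentage of the measured members of each of the 20 gene lists that were higher (red, to the right) or lower (blue, to the left) in treated than in control cells, per subset. Of the activation and immediate early list 17, 11, 16 and 14 of 23 members rose in Tconv, Treg, TFH and TFR cells.

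The subsets of control mice were compared next, to describe what separates the sorted populations in mice given PBS. Control Treg cells carried the regulatory program and more cytokine and proliferation transcripts than Tconv cells. Foxp3 was at 473 ± 30.6 against 5.81 ± 1.32 CPM (log2FC 6.35 ± 0.24, adjusted p = 1.4e-14), Ikzf2 at 640.2 ± 20 against 17.7 ± 3.83 CPM (log2FC 5.18 ± 0.14, adjusted p = 1.3e-16) and Ctla4 at 579 ± 7.88 against 35.8 ± 3.55 CPM (log2FC 4.01 ± 0.10, adjusted p = 3.7e-17). Il1rl1 (ENSMUSG00000026069.15), the IL-33 receptor, was at 74.8 ± 5.79 against 0.671 ± 0.371 CPM (log2FC 6.81 ± 0.65, adjusted p = 1.3e-07). Il10 (ENSMUSG00000016529.5), an anti-inflammatory cytokine, was at 100.3 ± 7.98 against 1.92 ± 0.513 CPM (log2FC 5.71 ± 0.28, adjusted p = 2.7e-12). Tnfrsf18, the gene of the sorted surface protein GITR, was at 227 ± 20.3 against 71 ± 12.7 CPM (log2FC 1.68 ± 0.14, adjusted p = 1.2e-08). Pdcd1 was at 222 ± 20.1 against 5.17 ± 1.86 CPM (log2FC 5.42 ± 0.19, adjusted p = 6.7e-15). Satb1 was lower, at 766 ± 11 against 2139 ± 298 CPM (log2FC -1.48 ± 0.10, adjusted p = 1.7e-10), as was Igfbp4 (ENSMUSG00000017493.12) at 9.53 ± 2.26 against 83.7 ± 13.2 CPM (log2FC -3.13 ± 0.24, adjusted p = 5.8e-08). Of the Treg program 23 of 26 were higher and 0 lower (24 and 0 adjusted over the list alone), camera adjusted p = 2.6e-183. Of helper and effector cytokines 12 of 28 were higher and 0 lower (15 and 0 adjusted over the list alone), camera adjusted p = 1.4e-23. Of proliferation genes 18 of 35 were higher and 1 lower (21 and 1 adjusted over the list alone), camera adjusted p = 2.6e-13. Of naive and recirculation genes 1 of 16 were higher and 8 lower (1 and 12 adjusted over the list alone), camera adjusted p = 4.5e-14. OX40 and NF-kB signalling was called upward with 9 higher and 1 lower of 25, or 11 and 1 adjusted over the list alone (camera adjusted p = 1.4e-07, or adjusted p = 0.060 with an estimated correlation), with Tnfrsf4 at 254 ± 6.02 against 27.5 ± 2.82 CPM (log2FC 3.21 ± 0.15, adjusted p = 5.5e-13). T cell identity, with 7 higher and 2 lower of 18, or 7 and 3 adjusted over the list alone, had a camera adjusted p of 0.0037, or adjusted p = 0.36 with an estimated correlation. Its direction turned without the 5 libraries (adjusted p = 0.71). Lower were 7 of 14 heat shock genes (0 higher) and 0 of 13 mitochondrially encoded mRNAs (1 higher). In total 1109 genes were higher and 638 lower (edgeR). 35% of tested genes had group values that did not overlap (10% by chance), and 29 of the lower genes were kidney-raised, including Gpx3, Nostrin, Pcdh19, Plxna2 and Ppl, the 5 lower genes that the naming rule selects. Without the 5 libraries, which leaves 1 control Tconv library, 538 were higher and 281 lower, 11 proliferation genes were higher, Il1rl1 had a log2FC of 8.18, and the fit of the 6 libraries compared gave 3308.

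TFR cells of control mice were set against TFH cells, the helper counterpart at the same site. The Treg program and proliferation genes were higher in TFR cells and B cell markers lower. Foxp3 was at 354 ± 39.6 against 47.3 ± 18.9 CPM (log2FC 2.88 ± 0.20, adjusted p = 2.4e-08), Ikzf2 at 999.7 ± 8.03 against 378 ± 32.1 CPM (log2FC 1.40 ± 0.12, adjusted p = 1.7e-07) and Tnfrsf9 (ENSMUSG00000028965.13), encoding the costimulatory receptor 4-1BB, at 632 ± 60.6 against 206 ± 25.4 CPM (log2FC 1.61 ± 0.12, adjusted p = 9.5e-08). Ctla4 was at 742 ± 67.5 against 447 ± 13.4 CPM (log2FC 0.73 ± 0.09, adjusted p = 1.2e-05), Tnfrsf18 at 192 ± 29.9 against 82.5 ± 11.9 CPM (log2FC 1.21 ± 0.14, adjusted p = 9.1e-06) and Top2a at 178 ± 8.49 against 58.1 ± 6.98 CPM (log2FC 1.63 ± 0.10, adjusted p = 2.5e-09). Aurkb (ENSMUSG00000020897.12), a mitotic kinase, was at 28.6 ± 2.06 CPM in TFR cells with 0 reads in TFH cells, at least 222-fold higher. Cxcr5 was at 53.7 ± 13.6 against 121 ± 22 CPM (log2FC -1.16 ± 0.23, adjusted p = 0.0024) and Tnfrsf4 at 267 ± 54.5 against 143 ± 29.6 CPM (log2FC 0.89 ± 0.14, adjusted p = 0.00020). In the fit of the 6 libraries alone these gave adjusted p of 0.12 and 0.081, with ranges of 7.3e-06 to 0.21 and 1.7e-09 to 0.31 over their alternatives. Of the Treg program 20 of 26 were higher and 0 lower (21 and 0 adjusted over the list alone), camera adjusted p = 8.7e-37. Of proliferation genes 20 of 35 were higher and 0 lower (22 and 0 adjusted over the list alone), camera adjusted p = 2.7e-25. In the fit of the 6 libraries alone 8 and 3 members of these lists were higher. Of B cell markers 0 of 21 were higher and 14 lower (0 and 15 adjusted over the list alone), camera adjusted p = 2.8e-09, with summed levels of 442 ± 36.7 against 611 ± 55.6 CPM. In the fit of the 6 libraries the smallest adjusted p of any member was 0.061. Naive and recirculation genes (2 higher and 6 lower of 16, or 4 and 8 adjusted over the list alone) and activation and immediate early genes (2 and 8 of 23, or 3 and 14) had camera adjusted p of 0.0011 and 0.0013 downward, or adjusted p = 0.20 and 0.27 with an estimated correlation. Lower were 9 of 14 heat shock genes (0 higher) and 7 of 13 mitochondrially encoded mRNAs (0 higher). In total 1470 genes were higher and 1503 lower (edgeR). 10.5% of tested genes had group values that did not overlap (10% by chance). The fit of the 6 libraries alone called 32 higher and 32 lower, and 898 of 18204 and 999 of 18215 genes were called in simulations without any change. Leaving out the 5 libraries gave 865 higher and 908 lower, with 8 B cell markers lower.

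TFH cells of control mice carried the follicular program relative to Tconv cells and fewer naive and recirculation transcripts. Cxcr5 was at 121 ± 22 against 1.83 ± 0.891 CPM (log2FC 6.05 ± 0.29, adjusted p = 1.1e-12), Bcl6 at 208 ± 29.9 against 52 ± 5.25 CPM (log2FC 2.00 ± 0.12, adjusted p = 7.1e-11) and Pdcd1 at 286 ± 17.6 against 5.17 ± 1.86 CPM (log2FC 5.78 ± 0.20, adjusted p = 2.5e-15). Tox2 (ENSMUSG00000074607.11), a TFH transcription factor, was at 164 ± 36.7 against 2.03 ± 0.112 CPM (log2FC 6.32 ± 0.24, adjusted p = 1.8e-14). Il21 was at 26.3 ± 10.9 against 1.28 ± 0.389 CPM (log2FC 4.35 ± 0.37, adjusted p = 1.4e-08). Satb1 was lower, at 250.0 ± 17.3 against 2139 ± 298 CPM (log2FC -3.10 ± 0.10, adjusted p = 1.5e-15). Klf2 (ENSMUSG00000055148.7), a regulator of lymphocyte egress, was at 55.8 ± 10.4 against 290.0 ± 29.6 CPM (log2FC -2.36 ± 0.13, adjusted p = 1.4e-11). Igfbp4 had 0 reads in TFH cells and 83.7 ± 13.2 CPM in Tconv cells, at least 648-fold lower. Of the TFH program 21 of 24 were higher and 0 lower (22 and 0 adjusted over the list alone), camera adjusted p = 1.3e-45. Of naive and recirculation genes 0 of 16 were higher and 14 lower (0 and 14 adjusted over the list alone), camera adjusted p = 4.3e-33. Of the Treg program 20 of 26 were higher and 1 lower (20 and 2 adjusted over the list alone), camera adjusted p = 1.3e-69. Foxp3 was at 47.3 ± 18.9 against 5.81 ± 1.32 CPM (log2FC 3.06 ± 0.21, adjusted p = 5.3e-10). Of B cell markers 13 of 21 were higher and 0 lower (15 and 0 adjusted over the list alone), camera adjusted p = 2.1e-10, at 611 ± 55.6 against 168 ± 23.7 CPM in sum. Lower were 9 of 14 heat shock genes (1 higher) and 2 of 13 mitochondrially encoded mRNAs (6 higher). In total 1858 genes were higher and 2843 lower (edgeR), with a median over all genes of -0.31. Thinning every library gave 1663 and 1681. 35% of tested genes had group values that did not overlap (10% by chance), 1255 of the lower genes had 0 reads in TFH libraries, and 86 were kidney-raised, among them Amotl1, Dab2, Ddn and Plxna2. The fit of the 6 libraries alone gave 608 higher and 1039 lower. In 2 simulations without any change, the 24-library fit called 909 of 18115 and 831 of 18136 genes. The fit of the 6 libraries alone called 4 of 13970 and 2 of 14018 in them. Leaving out the 5 libraries, which leaves 1 control Tconv library, gave a log2FC of 7.18 for Cxcr5.

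TFR cells of control mice differed from Treg cells in lower naive and recirculation genes and in higher TFH and proliferation genes. Satb1 was at 148 ± 19.6 against 766 ± 11 CPM (log2FC -2.37 ± 0.10, adjusted p = 2.0e-12), Ccr7 at 262 ± 29.2 against 758 ± 30 CPM (log2FC -1.53 ± 0.11, adjusted p = 1.9e-08) and S1pr1 (ENSMUSG00000045092.8), a receptor for exit from lymph nodes, at 154 ± 34.8 against 429 ± 0.849 CPM (log2FC -1.47 ± 0.12, adjusted p = 1.1e-07). Il12rb2 (ENSMUSG00000018341.12), a chain of the IL-12 receptor, had 0 reads in TFR cells and 32.1 ± 4.26 CPM in Treg cells, at least 264-fold lower. Cxcr5 was at 53.7 ± 13.6 against 16.3 ± 1.62 CPM (log2FC 1.73 ± 0.24, adjusted p = 8.5e-05), Bcl6 at 141 ± 15.5 against 79.2 ± 7.74 CPM (log2FC 0.83 ± 0.12, adjusted p = 0.00014) and Tox2 at 115 ± 34.3 against 32.2 ± 2.86 CPM (log2FC 1.83 ± 0.19, adjusted p = 5.2e-06). Dnase1l3 (ENSMUSG00000025279.7), a secreted DNase, was at 84.3 ± 11.9 against 2.74 ± 2.05 CPM (log2FC 4.94 ± 0.55, adjusted p = 9.7e-06). Foxp3 did not pass, at 354 ± 39.6 against 473 ± 30.6 CPM (adjusted p = 0.17), and Il2ra was lower, at 66.8 ± 3.60 against 113 ± 14.3 CPM (log2FC -0.76 ± 0.17, adjusted p = 0.0078). Of naive and recirculation genes 0 of 16 were higher and 13 lower (0 and 13 adjusted over the list alone), camera adjusted p = 1.9e-54. Of the TFH program 10 of 24 were higher and 0 lower (13 and 1 adjusted over the list alone), camera adjusted p = 1.1e-15. Of proliferation genes 9 of 35 were higher and 1 lower (15 and 2 adjusted over the list alone), camera adjusted p = 6.8e-17. CD8 and NK cell markers had 1 higher and 5 lower of 12, or 1 and 6 adjusted over the list alone, camera adjusted p = 0.0069. Co-inhibitory receptors were called upward with 4 higher and 2 lower of 16, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.0069), while their median was 0.23 and their mean -0.25. Lower were 5 of 14 heat shock genes (0 higher) and 1 of 13 mitochondrially encoded mRNAs (0 higher). In total 429 genes were higher and 1402 lower (edgeR), 618 and 1198 with relative log expression scaling, and 363 and 522 with every library thinned. 23.6% of tested genes had group values that did not overlap (10% by chance), and 623 of the lower genes had 0 reads in TFR libraries. The fit of the 6 libraries alone gave 207 higher and 256 lower. In 2 simulations without any change, the 24-library fit called 99 of 18194 and 13 of 18170 genes. The fit of the 6 libraries alone called 0 of 12808 and 0 of 12799 in them. The total was 1221 without control Treg 2 and 1118 without the 5 libraries.

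The last comparisons tested whether the treatment effect differed between subsets, as the difference of log2 fold changes. Naive and recirculation, immediate early, TFH and cytokine genes had a lower effect in Treg than in Tconv cells, where effect is the log2FC of treated against control. Tnfsf8 (ENSMUSG00000028362.2, chromosome 4, 63831308 to 63861347), encoding CD30 ligand, was at 224 ± 3.45 and 422 ± 18.1 CPM in treated and control Treg and 94.8 ± 5.66 and 21.9 ± 2.84 CPM in treated and control Tconv cells (log2 difference -3.03 ± 0.16, adjusted p = 2.0e-10). Ccr7 was at 183 ± 14.1 and 758 ± 30 CPM in treated and control Treg and 1081 ± 40.9 and 1218 ± 193 CPM in treated and control Tconv cells (log2 difference -1.88 ± 0.15, adjusted p = 1.9e-07). The log2 difference was -3.57 ± 0.35 (adjusted p = 2.0e-06) for Ifng and -2.97 ± 0.34 (adjusted p = 1.9e-05) for Il10. It was -2.51 ± 0.23 (adjusted p = 9.5e-07) for Pdcd1, which rose in treated Tconv and fell in treated Treg cells. Il2ra and Top2a went the other way, at 1.11 ± 0.25 (adjusted p = 0.017) and 0.62 ± 0.13 (adjusted p = 0.0097). Foxp3 (-0.82 ± 0.27, adjusted p = 0.10) and Tnfrsf4 (-0.05 ± 0.19, adjusted p = 0.99) did not pass. Of naive and recirculation genes 10 of 16 had a lower and 0 a higher effect in Treg cells (13 and 0 adjusted over the list alone), camera adjusted p = 1.2e-34. A lower effect was called for 11 of 23 activation and immediate early genes (16 adjusted over the list alone), 8 of 24 of the TFH program (11), 5 of 28 helper and effector cytokines (6) and 8 of 18 of T cell identity (13). The camera adjusted p of these lists was 7.8e-27, 5.6e-14, 7.9e-14 and 8.2e-23. A lower effect was also called for 2 of 14 heat shock genes and 3 of 13 mitochondrially encoded mRNAs. Proliferation genes had a higher effect in Treg cells in 6 of 35 and a lower one in 0 (11 and 0 adjusted over the list alone), camera adjusted p = 6.5e-11. In total 166 genes had a higher and 338 a lower effect in Treg cells (edgeR). Leaving receptor, haemoglobin and mitochondrial genes out of the scaling gave 165 and 179 and shifted the median of all genes by 0.15. Relative log expression scaling shifted it by 0.12. Of the 166, 25 were kidney-raised, including Ednrb, Gpx3, Plxna2, Tbx3 and Tjp1, the 5 the naming rule selects. Leaving out the 5 libraries keeps 1 control Tconv library. With the 5 libraries left out 13 and 95 passed the test, with 4 naive and recirculation, 4 activation, 6 TFH, 4 cytokine and 3 T cell identity genes lower, 1 proliferation gene higher and a log2 difference of -2.93 for Ifng. Ccr7, Ifng and Tnfsf8 then passed, whereas Il2ra and Top2a had adjusted p of 0.19 and 0.23 (ranges over all alternatives 1.7e-05 to 0.19 and 8.4e-08 to 0.23). The total depended on single libraries: it was 239, 247 and 1163 without control Tconv 1, 2 and 3, 275, 270 and 283 without control Treg 1, 2 and 3, 266, 255 and 268 without treated Tconv 1, 2 and 3, and 312, 303 and 253 without treated Treg 1, 2 and 3.

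Between TFR and TFH cells, Tnfrsf1b, Tnfrsf4, Il2ra and Batf had a higher effect in TFR cells. Tnfrsf1b (ENSMUSG00000028599.10, chromosome 4, 145213463 to 145246870), encoding TNF receptor 2, was at 366 ± 25 and 258 ± 47.8 CPM in treated and control TFR and 70.1 ± 3.04 and 203 ± 18.9 CPM in treated and control TFH cells (log2 difference 2.03 ± 0.16, adjusted p = 3.9e-07). Tnfrsf4 was at 410.3 ± 30.5 and 267 ± 54.5 CPM in treated and control TFR and 95.2 ± 5.37 and 143 ± 29.6 CPM in treated and control TFH cells (log2 difference 1.22 ± 0.19, adjusted p = 0.00069). The log2 difference was 1.89 ± 0.25 (adjusted p = 0.00014) for Il2ra, 1.23 ± 0.20 (adjusted p = 0.00085) for Batf, 1.72 ± 0.23 (adjusted p = 0.00014) for Cd74 and 0.55 ± 0.09 (adjusted p = 0.0010) for Atp5b. Bcl6, at -0.91 ± 0.17 (adjusted p = 0.0027), and Il21, at -1.53 ± 0.46 (adjusted p = 0.047), had a lower effect in TFR cells. In the fit of the 12 libraries compared, Batf, Bcl6, Atp5b and Il21 had adjusted p of 0.053, 0.062, 0.092 and 0.23. Over all alternatives these ranged over 9.6e-08 to 0.28, 2.4e-07 to 0.062, 1.4e-09 to 0.095 and 0.0024 to 0.23. Cdkn3 (ENSMUSG00000037628.9), a cell cycle phosphatase, had 0 reads in control TFR cells, 6.60 ± 0.336 CPM in treated TFR and 2.02 ± 0.120 and 4.89 ± 3.14 CPM in treated and control TFH cells (adjusted p = 0.00034). Cit had 0 reads in control TFH cells, 33.5 ± 2.46 CPM in treated TFH and 76 ± 6.23 and 28.9 ± 17.6 CPM in treated and control TFR cells (adjusted p = 0.00010). B cell markers had a higher effect in TFR cells in 2 of 21 (6 adjusted over the list alone), camera adjusted p = 4.9e-07. The Treg program (6 higher and 1 lower of 26, or 8 and 1 adjusted over the list alone), oxidative phosphorylation (4 and 0 of 33, or 7 and 0), glycolysis (3 and 0 of 19, or 5 and 0), the TFH program (1 and 6 of 24, or 1 and 8) and activation and immediate early genes (2 and 7 of 23, or 3 and 13) had camera adjusted p of 6.1e-05, 1.9e-05, 0.0025, 0.0056 and 0.00061. All 5 calls were lost with an estimated correlation (adjusted p = 0.095, 0.077, 0.15, 0.087 and 0.40). Notch genes were not called, with a camera adjusted p of 0.97. In total 620 genes had a higher and 705 a lower effect in TFR cells (edgeR), 42 and 43 in the fit of the 12 libraries compared, and 181 and 178 without the 5 libraries. No simulation without any change was run for this comparison. The total was 1993 and 2328 without control TFH 1 and 3, 709 without treated TFH 2, and 780, 698 and 660 without treated TFR 1, 2 and 3.

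**Figure D4:**
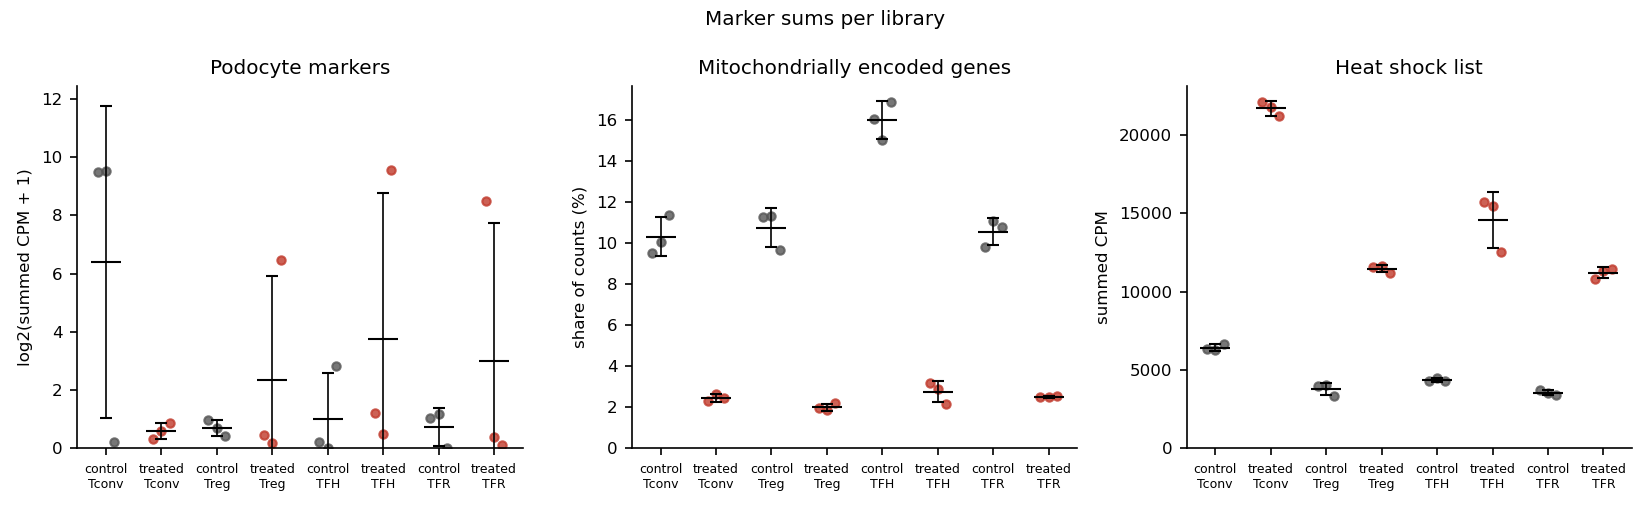
Summed podocyte markers, log2(CPM + 1), share of counts of mitochondrially encoded genes in percent, and summed heat shock genes in CPM, per library (points; grey control, red treated) with mean and SD (bars). Podocyte markers pass 10 CPM in 5 libraries of both arms, and the mitochondrial share lies at 1.85% to 3.17% in treated and 9.50% to 16.9% in control libraries.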

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

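The tests of a difference between treatment effects were planned. The splits of the libraries, the fit without the libraries with kidney transcripts and the tests of the kidney, mitochondrial and gene detection patterns were chosen only after the results were seen.

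The treatment effect differed between Treg and Tconv cells for 504 genes. Among the genes named, the log2 difference (effect in Treg minus effect in Tconv cells) was -0.75 for Bcl6, -1.88 for Ccr7, -1.41 for Ctla4, -2.40 for Cxcr3, -1.77 for Cxcr5 and -1.30 for Dusp1. It was -3.57 for Ifng, -2.97 for Il10, -2.85 for Il21, -1.45 for Jund, -2.51 for Pdcd1, -1.57 for Satb1 and -3.03 for Tnfsf8. It was 1.11 for Il2ra and 0.62 for Top2a, and 18.30 for Gpx3 and 15.15 for Tjp1, both of which are raised in the libraries with kidney transcripts. Gpx3 was at 14.4 ± 24.5 CPM in treated Treg, 0.0486 ± 0.0421 in control Treg, 0.210 ± 0.0160 in treated Tconv and 264 ± 231 in control Tconv libraries. Without the 5 libraries with kidney transcripts, which leaves 1 control Tconv library, the differences were 2.55 for Gpx3 and 3.69 for Tjp1. Those of Cxcr5 and Ifng were -2.81 and -2.93. The treatment effect differed between TFR and TFH cells for 1325 genes. The log2 difference there was 0.55 for Atp5b, 1.23 for Batf, -0.91 for Bcl6, 1.72 for Cd74, -1.53 for Il21, 1.89 for Il2ra, 1.07 for Tnfrsf18, 2.03 for Tnfrsf1b and 1.22 for Tnfrsf4.

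Other groupings of the same libraries were fitted for each count of genes. For a difference of effects, subset labels were exchanged within each treatment. For the Treg and Tconv effects, 8 of 100 splits gave at least 504 genes, the real one included, and the highest other split gave 1003. For the TFR and TFH effects, 12 of 100 gave at least 1325, and the highest other 2338. All other splits that gave as many, 7 and 11, left both subsets whole in 1 treatment, so they carry the difference between the subsets and do not bear on chance. In the 42 splits that moved as many libraries in treated as in control mice, the highest counts were 0 and 262, but their groups mix the subsets, which widens the spread. The splits therefore leave the part of chance in both counts undecided. The other comparisons have 10 splits each, too few for a share under 0.05. In each of them 1 split, the real one, gave the largest count. The real and highest other counts were 1868 and 12 for treatment in Tconv, 1640 and 0 in Treg, 4200 and 1 in TFH and 4134 and 0 in TFR cells. Between control subsets they were 1747 and 1 for Treg against Tconv, 2973 and 1791 for TFR against TFH, 4701 and 59 for TFH against Tconv and 1831 and 0 for TFR against Treg.

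Kidney transcripts stood out most in 5 libraries of both arms, with 0.302% to 2.22% of reads above the other libraries and up to 437 CPM of Gpx3, 335 of Kdr and 274 of Lrp2. OX40L-JAG1 treatment as their cause is argued against by a podocyte marker sum of 736 CPM in a control library. RNA of kidney cells is a candidate source, since across genes the raised profiles of any pair of the 5 libraries correlated at 0.957 or more. The marker lists were written before that test. In the remaining libraries 4 of 5 podocyte and 6 of 9 proximal tubule markers passed 1 CPM in any library. Their highest sums were 6.04 and 31.8 CPM, both in control TFH 3. A sort on surface CD4 would remove intact kidney cells, so cells passing the gate and RNA carried over at another step both stay open, and no biological explanation was tested.

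Treated libraries of every subset had a lower mitochondrial share and higher heat shock and immediate early mRNAs. A difference in library size is argued against, because the lowest share among the deep control Tconv and Treg libraries was 9.50%, against at most 3.17% in treated ones. A different share of mitochondrial, receptor and haemoglobin genes is argued against by heat shock calls, of which 53 of 56 were made with these genes left out and 53 with them. A difference in handling or library batch cannot be told apart from the treatment, because 0 libraries carry a batch, date or lane in their labels. An effect of the treatment itself stays open, as untested.

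Control TFH and TFR libraries showed fewer genes. Library size alone is argued against, since at equal depth the highest of the 6 had 13086 genes and the lowest of the other 18 had 14762. Few RNA molecules behind the reads may account for it, since reads that repeat the same molecules leave few genes at 1 to 3 reads. Their highest share of detected genes with 1 to 3 reads was 10.3%, against at least 19.2% elsewhere. A real difference in the number of genes expressed by the control subsets stays open, as untested.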

How the results depend on the processing

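The fits without the kidney libraries or also without control TFH 3, with thinning and with a minimum mean CPM were tests chosen only after the data were seen. Counts of genes past the threshold that stayed within 1.5 times the reported count are left out, and the cause of each change was not tested except where stated. The comparisons are treatment in the 4 subsets, subset against subset in control mice, and the difference of treatment effects. DESeq2 gave 3268 for Tconv cells, 2799 for Treg cells, 3232 for Treg against Tconv, 4866 for TFR against TFH, 3166 for TFR against Treg, 1491 for the Treg and Tconv effects and 3191 for the TFR and TFH effects. With limma voom it was 10500 for Tconv cells, 6500 for Treg cells, 1373 for TFH cells, 7910 for Treg against Tconv, 64 for TFR against TFH, 1805 for TFH against Tconv, 447 for TFR against Treg, 6980 for the Treg and Tconv effects and 46 for the TFR and TFH effects. Fitting only the libraries compared, which leaves fewer samples for the spread, gave 5629 for Tconv cells, 6190 for Treg cells, 1642 for TFH cells, 3308 for Treg against Tconv, 64 for TFR against TFH, 1647 for TFH against Tconv, 463 for TFR against Treg, 3157 for the Treg and Tconv effects and 85 for the TFR and TFH effects. Leaving out the 5 kidney libraries, which removes samples and leaves control Tconv cells with 1 library that is assumed to vary like the other groups, gave 576 for Tconv cells, 984 for Treg cells, 2169 for TFH cells, 2487 for TFR cells, 819 for Treg against Tconv, 1773 for TFR against TFH, 1721 for TFH against Tconv, 1118 for TFR against Treg, 108 for the Treg and Tconv effects and 359 for the TFR and TFH effects. Leaving out control TFH 3 as well gave 698 for Tconv cells, 996 for Treg against Tconv, 2439 for TFH against Tconv and 147 for the Treg and Tconv effects. Thinning gave 1784 for TFR against TFH, 885 for TFR against Treg and 828 for the TFR and TFH effects. A mean of at least 10 CPM, which tests fewer genes, gave 2724 for TFH cells, 1756 for TFR against TFH, 2988 for TFH against Tconv and 1173 for TFR against Treg. No low-count filter gave 1223 for the Treg and Tconv effects.

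Leaving out 1 library at a time gave 1172 to 2223 for Tconv cells, 1062 to 1119 for Treg cells, 3094 to 4578 for TFH cells, 3032 to 4081 for TFR cells, 1240 to 1809 for Treg against Tconv, 2918 to 3719 for TFR against TFH, 3463 to 5089 for TFH against Tconv, 1221 to 2155 for TFR against Treg, 239 to 1163 for the Treg and Tconv effects and 660 to 2328 for the TFR and TFH effects. Libraries that moved a count by over 1.5 times are named with each comparison above. Of called values of named genes, 2270 of 2556 kept direction and side of the threshold there, 372 of 374 with DESeq2, 383 of 386 with relative log expression factors, 379 of 386 without the filter, 320 of 386 with limma voom, 323 of 374 in the fits of compared libraries, 344 of 380 with thinning, 317 of 318 with the higher minimum, 364 of 373 without receptor, haemoglobin and mitochondrial genes, 324 of 386 without the kidney libraries and 336 of 386 without these and control TFH 3. All others lost the call. Ednrb in the Treg and Tconv effects also turned to -2.72 without the kidney libraries and -2.75 without control TFH 3 as well. With an estimated correlation 62 of the 200 list tests were called, against 108 with the preset one. Without the kidney libraries 166 list tests had the same direction and side of the threshold, called or not, 15 lost and 4 gained a call, and 14 that neither fit called changed sign. T cell identity in Treg against Tconv cells reversed there (adjusted p = 0.706). With fry 149 were the same in this sense, 36 gained and 4 lost a call, and 9 uncalled ones changed sign. The TFH program in treated TFH cells (adjusted p = 0.0175) and Notch genes in TFH against Tconv cells (adjusted p = 0.00780) reversed.

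Deviations from group means of 3 libraries cannot decide whether replicate numbers pair the libraries. Of 36 same-number pairs within a treatment, 5 correlated over 0.1 in these, and 6 of 24 libraries correlated best with their own number. With a replicate block over all groups the counts were 1794 for Tconv cells, 1480 for Treg cells, 3775 for TFH cells, 3797 for TFR cells, 1598 for Treg against Tconv, 2271 for TFR against TFH, 4293 for TFH against Tconv, 1517 for TFR against Treg, 373 for the Treg and Tconv effects and 924 for the TFR and TFH effects, all within 1.5 times the reported counts, and 368 of 386 called values of named genes kept their call. Of the list tests 196 were the same, 3 lost a call and 1 uncalled test changed sign. With a replicate block within each treatment the count was 1848 for TFR against TFH and 736 for the TFR and TFH effects, and 139 of 154 called values kept their call. By counting error alone, the floor of 3 reads over a group was 0.130 CPM in control TFH and 0.121 CPM in control TFR cells. It was 0.0200 to 0.0380 CPM in the other groups.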

Other observations

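The count of genes shared by the 4 treatment comparisons and the marker sums were tests chosen only after the results were seen. A core of genes moved the same way in all 4 subsets of treated mice. By edgeR's quasi-likelihood test 301 genes were higher and 132 lower in each treatment comparison, where independent lists would share 1.72 and 0.0764. The comparisons share no library, but they share the estimate of the spread and the arm in which any handling difference would fall. Of heat shock genes 12 of 14 were higher in all 4, of glycolysis genes 11 of 19, of activation and immediate early genes 8 of 23, of proliferation genes 5 of 35, of T cell identity genes 5 of 18 and of helper and effector cytokines 5 of 28. Lower in all 4 were 11 of 13 mitochondrially encoded mRNAs. The genes named here were picked after their values were seen. Hspa1b (ENSMUSG00000090877.3), an inducible chaperone, had log2 fold changes of 3.17 ± 0.13, 2.63 ± 0.12, 3.09 ± 0.13 and 2.78 ± 0.12 in Tconv, Treg, TFH and TFR cells. Lgals1 (ENSMUSG00000068220.5), encoding the lectin galectin-1, had 1.71 ± 0.28, 1.76 ± 0.28, 2.21 ± 0.29 and 1.65 ± 0.28. Cblb (ENSMUSG00000022637.10), a ubiquitin ligase that restrains T cell activation, had -0.97 ± 0.09, -1.28 ± 0.09, -1.21 ± 0.09 and -1.40 ± 0.09.

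Immunoglobulin genes, which encode antibodies, were among the shared genes: 16 of 156 tested were higher in all 4 comparisons. Ighm (ENSMUSG00000076617.9), the heavy chain of IgM, had log2 fold changes of 1.66 ± 0.12, 2.04 ± 0.12, 2.44 ± 0.12 and 2.51 ± 0.12, and Igkc 2.54 ± 0.16, 2.03 ± 0.15, 3.27 ± 0.16 and 3.76 ± 0.17. Of B cell markers 2 of 21 and of plasma cell markers 3 of 14 were higher in all 4. No explanation was tested.

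Of the kidney lists not given above, distal nephron markers summed to 9.47 to 67 CPM in the 5 libraries with kidney transcripts and 0 to 1.29 CPM in the other 19. Endothelial markers summed to 255 to 826 and 107 to 265 CPM, of which Pecam1, which lymphocytes also express, took up to 264 CPM in a library. Hepatocyte markers, of which 2 of 6 passed the low-count filter, summed to 0.314 to 1.51 and 0 to 1.90 CPM.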
